A study of Vitis vinifera with 6 samples.

How the data were processed

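The 6 libraries were made from RNA of seed traces or seeds with the TruSeq stranded mRNA kit, 15 PCR cycles and a mean fragment of 302 bp, per the labels' protocols. The authors deposited a single table of RPKM values, with 1 column per library and identifiers headed as the 12X V1 gene set. The submitters' processing notes name TopHat2 2.0.13, HTSeq 0.5.4p5 and edgeR 2.2.6 without giving the role of each, and the genome build and the strand setting of the counting were not given in the sources used here. RPKM divides by gene-model length and library total, so a gene's level is relative to all other reads of its library, and genes that share reads with near-identical copies, such as the chalcone synthases, are uncertain. Whether the totals behind the values were raw or adjusted between libraries is not settled.

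The table listed 29548 genes. Of these, 12 rows held a value with a doubled decimal point and were left out, which left 29536. Each column was assigned to its library through the sample descriptions, and classes were taken from the phenotype given in the labels. The titles of the seeded samples read Seededless, while their phenotype, genotype, tissue and description all mark them as seeds of seeded hybrids; the direction of every difference rests on these labels. For each gene the RPKM steps were searched for a length and library totals that turn all 6 values into whole reads. This worked for 23475 of the 24536 genes above 0 in any library (95.7%), and 22666 genes were taken as recovered after a chance fit above 0.01 was excluded. Tested on 6000 simulated genes, the search recovered 98%, and 98.9% of these had the true reads. The simulated genes took the lengths and levels of genes already recovered, so these shares do not cover the genes left unrecovered. Totals were 6576771 to 9267652 reads, which is a modest depth: a single read on a gene model of 1 kb is worth 0.108 to 0.152 RPKM. To look for a library deposited more than once, recovered reads were compared by chi-square, and the 15 pairs of libraries differed by 13.9 to 125.4 per degree of freedom; this covers counting error only and says nothing of the spread between plants.

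Genes with at least 1 RPKM in at least 3 libraries were tested (18749 genes). Values were taken as log2(RPKM + 1), which understates the change of low genes, and compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A 2-fold filter required an absolute log2 fold change of at least 1. In simulated data with the real means and class spreads and 200 changed genes among 18749, limma found 29 of 100 genes changed by 1 on the log2 scale, 62 of 100 changed by 2, and 9 of the 18549 unchanged genes. Gene lists were tested with limma's camera at a preset correlation of 0.01. Of 100 simulated lists of 18 unchanged genes 4 were called, and of 100 lists lowered by 1 on the log2 scale, 100. The simulated genes of both tests varied independently. The counts thus do not give the error rates where genes vary together, either for single genes or for lists. The correlation estimated for the flavonoid list was 0.177. Chromosomes, read from the identifiers with unplaced genes left out, and the window around VviAGL11 were compared with Fisher's exact test, two-sided. Whole-read recovery and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

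The table does not pair identifiers with names, and 0 of its identifiers matched the gene table of the reference used here (ASM3070453v1). The 20 gene symbols of the report, and 66 further symbols and a range of 39 identifiers used in the closing section, were therefore recalled from the published grapevine gene catalogue and not taken from a file. As a partial check, 13 of the 20 symbols occur in the reference table; 12 lie there on the chromosome that the identifier gives, and ANR has an unplaced identifier. Because no descriptions were given, 22 of 23 lists defined by product description were not used, and the flavonoid list was tested on its 19 recalled genes alone, so no adjustment over lists applied. The tests of the report, the 20 recalled genes, the flavonoid list, the naming rule and the alternatives, apart from those said to be added, were fixed before the data were examined. The 66 further symbols, the range of identifiers and most tests of the closing section were chosen later, as stated there. The rule named the 20 recalled genes plus, without descriptions, the 2 largest rises and 2 largest falls among genes past the threshold whose classes did not overlap and whose higher class averaged at least 10 RPKM.

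Alternatives changed the pseudocount (0.1 and 0.5), the filter (none, or 5 RPKM), the scaling (quantile normalization, or medians), the variance model, library weights, a block on replicate number, the threshold, the set test and the window (50 and 250 genes), and left out each library in turn. Limma's voom on the recovered reads and the window at an adjusted p of 0.01 were added after the data were seen.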

Results

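RNA from the seed content of young grape berries was sequenced in 6 libraries. Grapevine seedlessness of the stenospermocarpic kind leaves a small seed trace, because the seed starts to form and then stops. All plants were F1 hybrids of the table grapes Red Globe and Crimson Seedless. Of these, 3 seedless hybrids (labelled sdi+) gave seed traces and 3 seeded hybrids (labelled sdi-) gave seeds. Every library came from another hybrid, so the spread within a class holds differences between plants as well as technical error. Berries were sampled 4 weeks after anthesis at a diameter of 10 to 12 mm, and each library pooled the seed content of 12 to 50 fruits. Expression is given as RPKM, a read count divided by gene-model length and library total. The read totals recovered from the steps of the low RPKM values were 7167559, 7470208 and 6576771 for seedless replicates 1 to 3, and 7811602, 9267652 and 7494970 for seeded replicates 1 to 3. At these depths 3 reads on a gene model of 1 kb correspond to 0.324 to 0.456 RPKM, which covers counting error only.

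The 3 seeded libraries resembled each other closely, with Pearson correlations of 0.959 to 0.961 across genes on the log2 scale. Seedless replicates 2 and 3 correlated at 0.944, whereas seedless replicate 1 correlated with them at 0.847 and 0.862. The correlation of seedless replicate 1 with the seeded libraries was 0.728 to 0.743. Seedless replicates 2 and 3 correlated with the seeded libraries at 0.866 to 0.889, which is above their correlations with seedless replicate 1. The first principal component held 64% of the variance and placed all seedless libraries on one side and all seeded libraries on the other, with seedless replicate 1 at the far end. These are correlations across genes, which are not independent replicates.

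**Figure D1:**
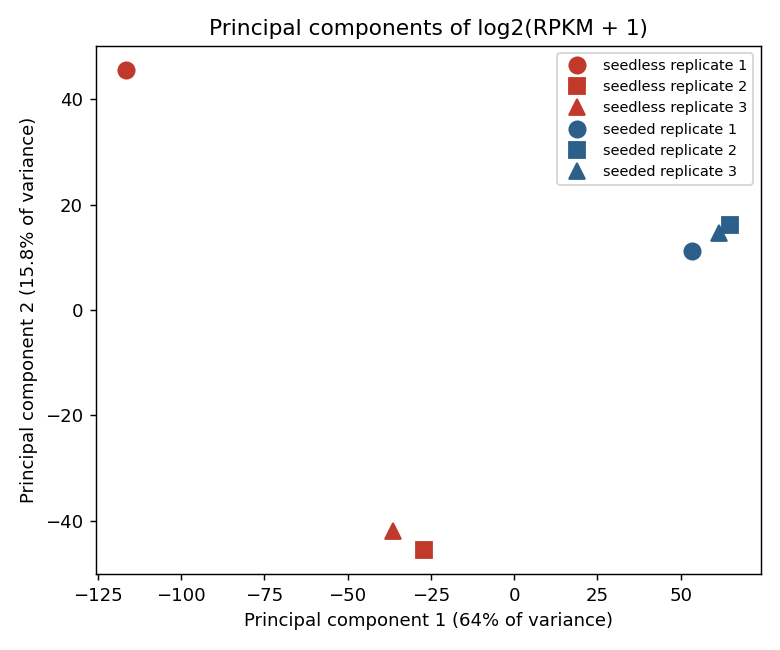
Principal component 1 (x axis, 64% of the variance) against component 2 (y axis, 15.8%) of log2(RPKM + 1), 1 point per library, red for seedless and blue for seeded hybrids. The classes separate on component 1, where seedless replicate 1 lies at -116.5 and the other seedless libraries at -27 and -36.3. On component 2 seedless replicate 1 lies at 45.6, the other seedless libraries at -45.6 and -42, and the seeded libraries at 11.3 to 16.1.

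The comparison of the classes asks which genes differ in the seed at a stage when seedless hybrids hold only traces. Of 19 listed genes of flavonoid and proanthocyanidin synthesis, the pathway that makes the tannins of the seed coat, 18 were expressed above the filter, 10 fell in seed traces, none rose and 8 did not pass (limma, adjusted p under 0.05). Limma's camera test placed the list below the rest of the genes (p = 2.68e-06 with a preset correlation of 0.01), and the call was lost at p = 0.0642 with an estimated correlation. Adjusted over the list alone, 14 fell and 1 rose. The median log2 fold change of the list was -1.13, on the log2(RPKM + 1) scale used throughout.

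Chalcone synthase, the entry enzyme of the pathway, was represented by 3 genes. CHS1 (VIT_14s0068g00930) stood at 154.5 ± 57.1 RPKM in seedless traces and 497.9 ± 80.3 in seeds (SD, n = 3 each), a log2 fold change of -1.73 with an SE of 0.29 and a limma adjusted p of 0.0177. CHS2 fell as well, by 1.27 on the log2 scale (limma adjusted p = 0.042), while CHS3 had a log2 fold change of -0.92 that did not pass (limma adjusted p = 0.0542). Downstream, flavonoid 3'-hydroxylase (F3'H, VIT_17s0000g07200) had 139.5 ± 5.72 RPKM against 348.6 ± 38.9 (SD, n = 3 each), and its log2 fold change of -1.31 gave a limma adjusted p of 0.00674. The flavanone 3-hydroxylase F3H1, the chalcone isomerase CHI2 and dihydroflavonol reductase (DFR) fell too, with log2 fold changes of -1.32, -1.23 and -1.47. LDOX, F3H2 and CHI1 had log2 fold changes of -0.92, -0.89 and -0.56 and did not pass.

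The enzymes that commit the pathway to proanthocyanidins were anthocyanidin reductase (ANR) and leucoanthocyanidin reductase 1 (LAR1). ANR had 108.4 ± 16.1 RPKM in seedless traces and 225.4 ± 47.7 in seeds, and LAR1 had 32.4 ± 13.8 against 118.4 ± 47.8 (SD, n = 3 each). Their log2 fold changes were -1.04 and -1.84, with limma adjusted p of 0.0267 and 0.0309. LAR2 went the other way, at 39.5 ± 31.5 RPKM in traces and 9.70 ± 3.23 in seeds, and its log2 fold change of 1.70 missed the threshold over all genes (limma adjusted p = 0.0799) but passed adjusted over the list alone. Seedless replicate 1 had 75.9 RPKM of LAR2 and the other seedless libraries 21.5 and 21.1, and without it the log2 fold change was 1.11. The MYB factors MYBPA1 and MYBPA2, known activators of proanthocyanidin genes, fell with log2 fold changes of -1.34 and -1.82, although MYBPA2 reached only 4.06 ± 1.06 RPKM in seeds (SD, n = 3). MYBPA2 lost the threshold in 7 of 16 alternatives (limma adjusted p of 0.00501 to 0.0929), among them a pseudocount of 0.1, where its log2 fold change was -3.46, and voom on recovered reads, where it was -3.68. MYB5a, MYB5b and flavonol synthase 1 (FLS1) had log2 fold changes of 0.67, -0.08 and -0.14 and did not pass. Without seedless replicate 1 these were 0.26, -0.75 and 0.99, so that FLS1 turned direction, and again none passed. The glycosyltransferase UFGT, which makes anthocyanins, was below the filter, with at most 0.372 RPKM in any library.

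Without seedless replicate 1, 2 or 3 the list had 9, 6 and 6 falls, with medians of -0.96, -1.15 and -1.2, and without seeded replicate 1, 2 or 3 it had 2, 2 and 1 falls, with medians of -1.19, -1.21 and -0.97. Under quantile normalization 7 genes fell, and CHS2, CHI2 and ANR no longer passed (limma adjusted p = 0.103, 0.0958 and 0.0531); CHS2 lost the threshold in 8 of 17 alternatives, over which its adjusted p was 0.027 to 0.136.

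**Figure D2:**
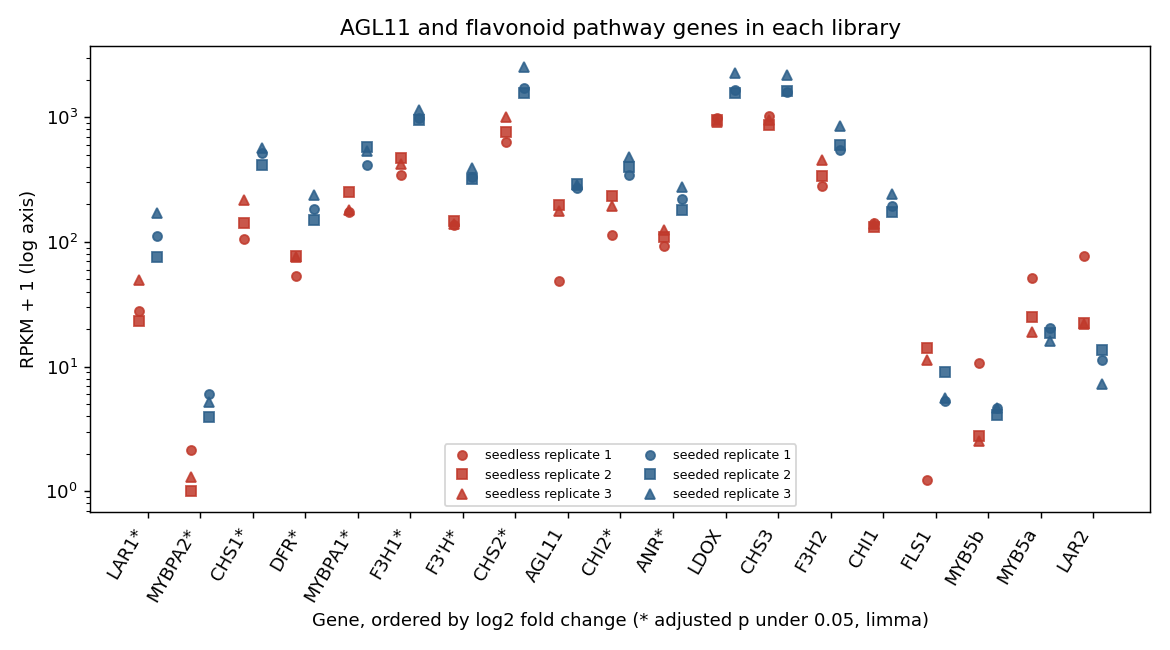
RPKM + 1 on a log axis for AGL11 and the 18 flavonoid genes above the filter, 1 point per library, red for seedless and blue for seeded hybrids, ordered by log2 fold change; an asterisk marks limma adjusted p under 0.05. The seedless libraries overlap the seeded ones for MYB5a, MYB5b and FLS1, lie above them for LAR2 and lie below them for all other genes shown.

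VviAGL11 (VIT_18s0041g01880) is the MADS-box gene reported at the major seedlessness locus of chromosome 18. It had 47.5, 197 and 177 RPKM in seedless replicates 1 to 3 and 272, 288 and 287 RPKM in seeded replicates 1 to 3. The class means were 140.5 ± 81.2 and 282.3 ± 9.24 RPKM (SD, n = 3 each), so each seedless library was below each seeded library. The log2 fold change of -1.24 (SE 0.52) did not pass (limma adjusted p = 0.161). Without seedless replicate 1 the log2 fold change was -0.59 and passed (limma adjusted p = 0.0373). Over all alternatives the limma adjusted p was 0.0373 to 0.318.

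Across the transcriptome, 2303 of 18749 genes differed between the classes (limma, adjusted p under 0.05), of which 1346 rose and 957 fell in seedless traces, or 58.4% rises. Quantile normalization gave 1062 rises and 1042 falls, or 50.5% rises. With at least a 2-fold change there were 1155 rises and 523 falls, or 68.8% rises, and quantile normalization gave 903 and 658, or 57.8%. Of the 1155 rises, 447 genes had a mean under 1 RPKM in seeds, and of the 523 falls, 69 genes had a mean under 1 RPKM in traces. The gene with the largest rise by the naming rule, VIT_05s0077g01580, had 577, 73.8 and 87.4 RPKM in seedless replicates 1 to 3 and 0.174, 0.293 and 0 in seeded replicates 1 to 3. VIT_18s0001g15220 followed with 305, 62.7 and 62.1 RPKM against 0.104, 0.437 and 0. Among the falls, VIT_14s0108g00420 was listed at 0, 8.28 and 2.69 RPKM in traces and at 72.2, 157.9 and 153.2 in seeds, and VIT_12s0028g00840 was listed at 0 in each seedless library and at 30.2, 22.6 and 39.1 in the seeded ones. The files do not pair these 4 identifiers with names. Both rises missed the threshold with voom on recovered reads, where their log2 fold changes were 9.53 and 9.32 (limma adjusted p = 0.105 and 0.0627) against 7.09 and 6.52. VIT_14s0108g00420 missed it without seeded replicate 2 or 3 (limma adjusted p = 0.0649 and 0.0615).

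The classes did not overlap for 7409 genes, 39.5% of those tested, where 10% is the average share that chance gives for 3 against 3. Genes vary together across libraries, so a single split can lie far from that average by chance. Without seedless replicate 1 the test gave 1670 rises and 1239 falls; without seedless replicate 3 the total was 1367, and without seeded replicate 1, 2 or 3 it was 672, 429 and 449. A test of 3 against 3 by exact permutation cannot give a p below 0.1 for any single gene.

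**Figure D3:**
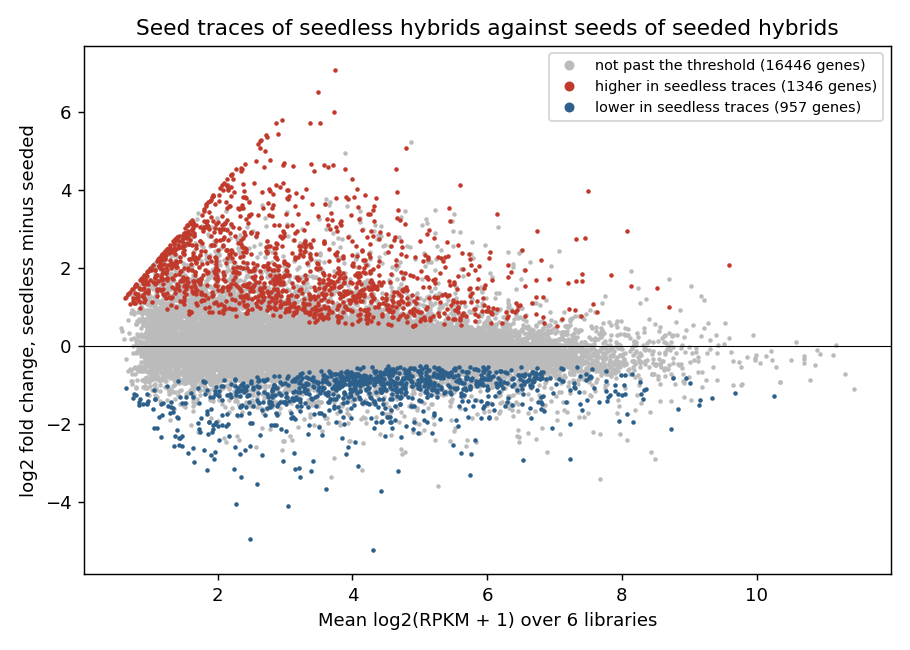
Log2 fold change, seedless minus seeded (y axis), against the mean log2(RPKM + 1) of the 6 libraries (x axis), 1 point per gene tested, red for the 1346 genes that rose and blue for the 957 that fell (limma adjusted p under 0.05). The rises reach further from 0 than the falls among genes of low mean expression.

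The labels give the classes as sdi+ and sdi-, and the major seedlessness locus is reported on chromosome 18, so changed genes were counted there and around VviAGL11. On chromosome 18, 188 of 1430 tested genes changed (13.1%), against 12.3% of genes on the other chromosomes, an odds ratio of 1.08 (95% interval 0.91 to 1.27; Fisher's exact test, two-sided, adjusted p = 0.821 over 19 chromosomes). Chromosomes 3, 12 and 13 had more changed genes than the rest, at 16.1%, 15.7% and 15.1%. Chromosomes 7 and 11 had fewer, at 9.8% and 9.1%. For these chromosomes the adjusted p was 0.0228 to 0.0284 in Fisher's exact test. That test counts genes as independent, whereas linked or co-expressed genes may change together. Its p-values, here and for the window below, thus do not measure the spread between hybrids. Of the chromosomes, only 18 was carried through the alternatives. Within 100 genes on either side of VviAGL11 in identifier order, 14 of 90 tested genes changed (15.6%), against 12.3% elsewhere, an odds ratio of 1.32 (95% interval 0.69 to 2.35; Fisher's exact test, two-sided, p = 0.334). Identifier order follows position only within a scaffold, and 148 of the 200 neighbours share the scaffold of VviAGL11. Without seeded replicate 1, 2 or 3 the odds ratio rose to 2.64, 4.23 and 4.03, with 8 changed genes in the window each time (Fisher's exact p = 0.0154, 0.00106 and 0.00142). At adjusted p under 0.01, a threshold added here after the data were seen, 7 of the 90 genes changed (7.8%) against 1.8% elsewhere, an odds ratio of 4.5 (95% interval 1.74 to 9.79; Fisher's exact p = 0.00148).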

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

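The voom fit and the window at adjusted p under 0.01 were chosen after the data were seen. Of the counts, 350 genes passed at adjusted p under 0.01, 3603 with library weights, and 429 to 2909 when a library was left out. With at least a 2-fold change, the count was 124 by treat against 2-fold and 424 to 1927 when a library was left out. Among the fits that left out a library, those without a seeded library gave the lowest counts, and the cause was not tested. All other settings kept both counts within 1.5 times. Limma's voom on recovered reads called 1694 genes, 1657 of them shared with the 2303. It covered only those tested genes whose reads were recovered, 17 in place of 18 for the flavonoid list. For the flavonoid list, camera's p was 0.0642 with an estimated correlation, 6.73e-07 to 2.46e-05 when a library was left out and 0.00093 by fry, which tests movement one way without comparing the list to other genes. The log2 fold change of VviAGL11 was -1.61 to -0.59 when a library was left out, and was past the threshold only at -0.59, without seedless replicate 1. The odds ratio of the window around VviAGL11 was 1.32 to 4.23 when a library was left out and 4.5 at adjusted p under 0.01. It passed without any 1 of the seeded libraries and at that threshold, and the cause was not tested. These passes are not separate support, since the fits share libraries. Without seeded replicate 1, 2 or 3 and at adjusted p under 0.01, the calls over all genes went from 2303 to 672, 429, 449 and 350. The window then held 8, 8, 8 and 7 calls. Fisher's exact test also counts neighbouring genes as independent. The odds ratio of chromosome 18 stayed at 1 to 1.4 and did not pass under any setting run. For the named genes, 309 of the 371 comparisons with an alternative kept direction and side of the threshold, 45 lost the threshold and 12 gained it. In the remaining 5 the fold change of FLS1 or MYB5b, which passed in neither fit, turned direction.

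With the replicate block, 1714 genes passed, 1395 of them with at least a 2-fold change, and the calls on VviAGL11, chromosome 18, the window and the flavonoid list by camera were the same. Of the list, 11 genes fell in place of 10, since F3H2 passed (limma adjusted p = 0.0434, range over its alternatives 0.0434 to 0.211). The labels name a different hybrid for every number. Deviations of same-numbered libraries from their class means correlated at 0.07, 0.18 and 0.1 across genes, and each library correlated best with the library of its own number. These correlations are low, and they are not independent, since the deviations cancel out within a class. Their chance level was not worked out. They are at most a weak hint from the data and not from the design.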

Other observations

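The lists and tests of the next 2 paragraphs were chosen after the data were opened, and VviAG1 after its values were seen. MADS-box genes of the floral and ovule classes differed in both directions. VviAG1 (VIT_12s0142g00360), an AGAMOUS-class gene, stood at 7.45 ± 1.12 RPKM in seedless traces and 77.2 ± 10.9 in seeds (SD, n = 3 each), a log2 fold change of -3.21 (limma adjusted p = 0.00142). VviAG2, VviSEP1 and VviFUL2 fell as well, with log2 fold changes of -1.06, -2.23 and -2.34, while VviSEP2 rose from 3.77 ± 0.518 to 12.2 ± 2.73 RPKM (SD, n = 3 each). Of 12 listed genes 7 were above the filter, 4 fell, 1 rose and 2 did not pass, and the same counts held without seedless replicate 1. VviAGL11, which did not pass in the fit of all libraries, was not among the 12 listed genes. Camera gave an adjusted p of 0.0133 over 4 lists, and the adjusted p was 0.156 with an estimated correlation. The list holds VviAG1, whose values were seen before it was chosen, so camera's p rests in part on that choice. No value of the test without VviAG1 is given here.

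Phenylalanine ammonia-lyase (PAL) and cinnamate 4-hydroxylase (C4H) are the entry enzymes of phenylpropanoid synthesis. Of 14 listed genes 7 were above the filter, 4 fell, none rose and 3 did not pass; 3 fell without seedless replicate 1 and 2 under quantile normalization. The 2 PAL copies of chromosome 16 above the filter, VIT_16s0039g01100 and VIT_16s0039g01130, were low and had log2 fold changes of 0.99 and 0.22 that did not pass, or 0.37 and 0.11 without seedless replicate 1. The PAL gene VIT_06s0004g02620 had 354.2 ± 34.2 RPKM in traces and 920.6 ± 78 in seeds, and the C4H gene VIT_06s0004g08150 had 546.8 ± 86.9 against 1252 ± 200.3 (SD, n = 3 each). Camera gave an adjusted p of 0.0133, and 0.156 with an estimated correlation. In a list of flavonoid regulators and transporters, 12 of 16 genes were above the filter; the MYB repressor gene MYBC2-L3 and the transporter gene AM1 rose, with log2 fold changes of 2.85 and 2.22 (limma adjusted p = 0.00615 and 0.0069), none fell and 10 did not pass, although 1 fell under quantile normalization. Camera gave an adjusted p of 0.215 for this list and 0.624 with an estimated correlation. Among 8 sugar transport and hormone genes none passed, and camera gave an adjusted p of 0.681. Of 14 copies of flavonoid 3',5'-hydroxylase 3 were above the filter and none passed, and the 39 genes of the stilbene synthase cluster and 2 of their regulators were below the filter, with at most 2.19 and 5.65 RPKM. Copies within a family can share reads, so their single values are uncertain.

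Of the tests below, those of depth, mislabelling, shared direction, the single library and the flavonoid list were chosen after the values they measure had been seen. Seedless replicate 1 stood apart: 314 genes were over 4-fold above and 293 over 4-fold below both other seedless libraries, against at most 30 and 126 for any other library. Lower depth is argued against, since its recovered total of 7167559, which may be raw or adjusted, lies within the range of the others. Its 6949077 reads recovered in genes also lie within the 5938487 to 8853565 of the other libraries. Uneven loss of long or short transcripts is argued against too, since the deviation had a Spearman rho of 0.046 with gene-model length across 17739 genes. A label swapped with a seeded sample is argued against by its mean correlation of 0.735 with the seeded libraries against 0.855 with the seedless ones. Its difference from another seedless library was set against the difference between the remaining seedless library and the seeded mean, which shares no library with it. These correlated at 0.24 and 0.31 across genes. A further change in the direction that separates the classes would give this for part of the deviation. On component 2 seedless replicate 1 lay at 45.6, the other seedless libraries at -45.6 and -42, and the seeded ones at 11.3 to 16.1. Its deviation was thus not along component 1 alone. Whether the deviation reflects the hybrid, a later stage of arrest or other tissue in the pooled seed content was not tested. It may be asked of further hybrids.

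More genes were at least 2-fold higher than lower in seedless traces. Scaling of the libraries cannot be told apart as a source, because the ratio of rises to falls was 1.37 under quantile normalization and 2.43 under median scaling, against 2.21 as deposited. A single library is argued against, since the ratio was 2.24 without seedless replicate 1. The difference in tissue between traces and seeds, which the design names, stays open and untested.

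For the lower flavonoid genes, seedless replicate 1 alone is argued against as the source by the median log2 fold change of -0.96 without it, against -1.13 with it. Another bound asked for at least as many falls without seedless replicate 1. It was missed by 1 gene, with 9 falls against 10, and that count by itself leaves the question open. Both the median and the count were judged by bounds set after the values were seen. A difference in the share of seed coat in the pooled tissue may lower such genes together and was not tested.

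For the counts of changed genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 2303 genes, and the highest of the other splits gave 1. With at least a 2-fold change the real split, 1 of 10, gave 1678 genes and the highest other gave 1. A total of 10 splits is too few for a share under 0.05.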
